A study of Mus musculus with 8 samples.

How the data were processed

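The data are 8 RNA sequencing samples of sorted thymocytes from C57BL/6 mice, in 4 groups of 2 (WT DP1, Hdac3KO DP1, WT DP2 and Hdac3KO DP2), where the cells were GFP+ CD4+CD8+ and DP1 and DP2 were parted by surface CD5 and TCRβ. Per the labels, total RNA was extracted with Trizol, depleted of ribosomal RNA and made into stranded libraries with a Clontech SMARTer kit from RNA pools. The submitters' processing notes name Trimmomatic 0.32, TopHat2 2.0.11, Cuffdiff 2.1.1 and the mm10 genome. Settings and the gene annotation are not stated there. The deposited files are 4 Cuffdiff tables, each comparing 2 of the groups (genotypes in DP1, genotypes in DP2, stages in WT and stages in Hdac3KO).

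The deposited FPKM are 1 value per gene and group, normalized between the 2 groups of each table only. The same group's FPKM therefore differ between deposited tables, and their median ratios between tables were 1.13 for WT DP1, 0.963 for WT DP2, 1.00 for Hdac3KO DP1 and 0.908 for Hdac3KO DP2. The authors' test statistic is the score that Cuffdiff gives with each comparison. The authors' deposited p-value has a smallest value of 5e-05, and the deposited q-value was checked to equal the Benjamini-Hochberg adjustment of the tested genes, with a largest difference of 5.26e-07. The deposited log2 column was damaged by a spreadsheet, so log2 fold changes were computed from the deposited FPKM. In the same way 25 symbols had become dates and were not matched to genes, and 89 entries join more than 1 gene. Total counts per library were not used here, so the depth per library is unknown and no binomial interval is given. Whole read counts could not be recovered from low FPKM, since the commonest ratio among genes under 0.3 FPKM was shared by 57 of 4813 such genes in the DP1 genotype table and by 113 of 3750 in the DP2 genotype table.

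The main test of each comparison is the authors' deposited q at 0.05, because 1 value per group leaves no spread to test anew. Standard errors are the size of the log2 change divided by the normal quantile of the deposited p. They are upper bounds where p is at its smallest, 5e-05, and imprecise where p is near 1. The deposited statistic was not used for them, since at p between 0.045 and 0.055 its median size was 1.46, 1.33, 1.34 and 1.30 in the 4 tables, where a normal quantile is 1.96. A difference between comparisons (the interaction) was tested as the difference of the log2 changes over the root of the summed squared SE, with a normal p, two-sided, and Benjamini-Hochberg adjustment. It was computed by 2 routes, from the genotype tables and from the stage tables, which rest on the same libraries. This procedure was tested on simulated data, with normal errors of the size that the test assumes and no trend on length or GC. The rates that follow therefore do not show whether the SE worked back from the deposited p are right. Differences of 1, 2 and 3 on the log2 scale were called for 6.67%, 40% and 68% of genes by the genotype route and for 8%, 25.3% and 40% by the stage route, and 0.0201% and 0.0307% of unchanged genes were called.

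Named genes were chosen by a rule set before the data were examined: the 10 genes with the largest log2 change in each direction among called genes with at least 5 FPKM in the higher group and no value of 0. Joined entries were left out, as were symbols that match set patterns of small RNA genes (Mir, Snor, Scarna, Rnu, Rny, Rpph, Rmrp and n-R5s) and of unnamed loci (Gm, Rik, LOC, and 2 letters with 6 digits). Rprl3, a small RNA gene, and the locus C85492 match none of these patterns and therefore stayed in. Examples from the lists are the called members with the largest changes, and members given as not passing were chosen after their values were seen, as were the gene families and further list members. The 28 gene lists, 21 of pathways and 7 of cell type markers, hold 615 symbols, of which 594 are in the tables. They were also fixed then. A list's calls were counted over its tested genes, by the deposited q and adjusted over the list alone. Its median covers members with at least 1 FPKM in either group, is relative to the median of genes with at least 10 FPKM in both groups, and was set against 10000 random lists drawn from the same 20 expression bins, whose limits are their lowest and highest 2.5%. Fisher's exact test compared called and other genes between each list and the remaining tested genes, adjusted over 56 tests per table (28 lists, both directions). Transcript length and GC content are those of the longest transcript in GENCODE M21 on mm10, and positions count from 1. The length trend was removed with a lowess curve (fraction 0.3) over genes with at least 10 FPKM in both groups, and the trend with GC content in the same way.

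Alternatives were a q of 0.01 and of 0.10, a log2 change of at least 1, adjustment over all 4 tables, centring on the median gene, the normal p of the deposited statistic, SE from that statistic, SE multiplied by 1.5, a minimum of 5 FPKM, a pseudocount of 1 or 0.1, no small RNA genes, and agreement over called genes only. Removal of the length trend, removal of the GC trend and omission of genes on X and Y were added after the data had been seen. Values of a few single genes are not reported here. Samples were not split otherwise, since groups of 2 with 1 value each allow no other grouping. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.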

Results

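RNA from sorted mouse CD4+CD8+ double-positive thymocytes was sequenced to ask which transcripts depend on Hdac3, the histone deacetylase of the NCoR and SMRT corepressor complexes, at an early and a later point of this stage. The early population, DP1, had low surface CD5 and low TCRβ. The later population, DP2, had high CD5 and intermediate TCRβ, levels that thymocytes reach once their T cell receptor (TCR) has begun to signal in selection. Each population came from wild-type (WT) animals and from animals with floxed Hdac3 alleles and Cre driven by LCK (Hdac3KO), which gave 4 groups of 2 libraries and 8 samples in all. The deposited values are 1 FPKM (a fragment count scaled by transcript length and library size) per gene and group, in 4 tables that each compare 2 groups and list 23278 genes. Total counts per library were not used here, so the depth behind each value is unknown, and no spread between libraries could be computed. The p-values and q-values are those of the authors' deposited tables. They measure only the spread between these libraries, which were made from RNA pools. A gene was called changed at a deposited q of 0.05 or less. Each log2 fold change is followed by a standard error (SE) worked back from the deposited p.

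Hdac3 itself (mm10 chromosome 18, 37935844 to 37955016, minus strand) was lower in the knockout at both points. In DP1 it fell from 38.1 FPKM in WT to 11.7 in Hdac3KO in the authors' deposited table, a log2 change of -1.70 ± 0.42 (q = 0.000879) that left 30.7% of the WT value. DP2 cells went from 29.7 to 15.4 FPKM in the authors' deposited table, -0.95 ± 0.28 (q = 0.0131), with 51.9% of the WT value left. A gene-level value also counts transcripts that lack only the deleted exons. The difference between these effects was 0.76 ± 0.51 and did not pass the normal test of the difference (q = 0.42). From DP1 to DP2, Hdac3 changed by -0.60 ± 0.29 in WT (q = 0.117) and by 0.26 ± 0.26 in Hdac3KO (q = 0.745) in the authors' deposited tables, neither of which passed. Of the 19 measured genes of histone deacetylases and their corepressors, 3 were higher and 2 lower in Hdac3KO DP1. Adjusted over the list alone these were 4 and 2, relative to the median gene 6 and 2, and the median of the list was 0.08 relative to the median gene. In Hdac3KO DP2 7 were higher and 2 lower, with the same counts adjusted over the list alone and a median of 0.11, inside the limits of random lists. The higher genes were in excess by Fisher's exact test (adjusted p = 0.00105) and the lower ones were not (adjusted p = 0.441). Tbl1xr1, which encodes a subunit of the NCoR complex, rose from 28.9 to 100.3 FPKM in DP1 and from 36.5 to 95.1 in DP2 in the authors' deposited tables. Hdac7, a class IIa deacetylase of thymocytes, rose from 105 to 224 FPKM in DP2 in the authors' deposited table, and Hdac11 from 0.916 to 3.68.

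Loss of Hdac3 in DP1 cells was set against WT DP1 cells to find the genes that depend on it before strong TCR signalling. Genes of the cell cycle were lower and several genes of TCR signalling were higher. Several genes that TCR signals induce, among them Pdcd1, Egr1 and Id3, were already lower at this point. The GTPase genes Gimap3, Gimap4 and Gimap7, which mark more mature thymocytes, were higher than in WT. In the authors' deposited table, 1120 genes were higher and 1358 lower in Hdac3KO, 23.6% of the 10511 tested, and 618 and 594 of these differed at least 2-fold. The median gene lay at -0.11, and relative to it the split was 1431 higher and 947 lower, so the direction of the majority depended on the scaling. Fold changes also followed transcript length here, and with that trend removed 939 genes were higher and 591 lower.

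**Figure D1:**
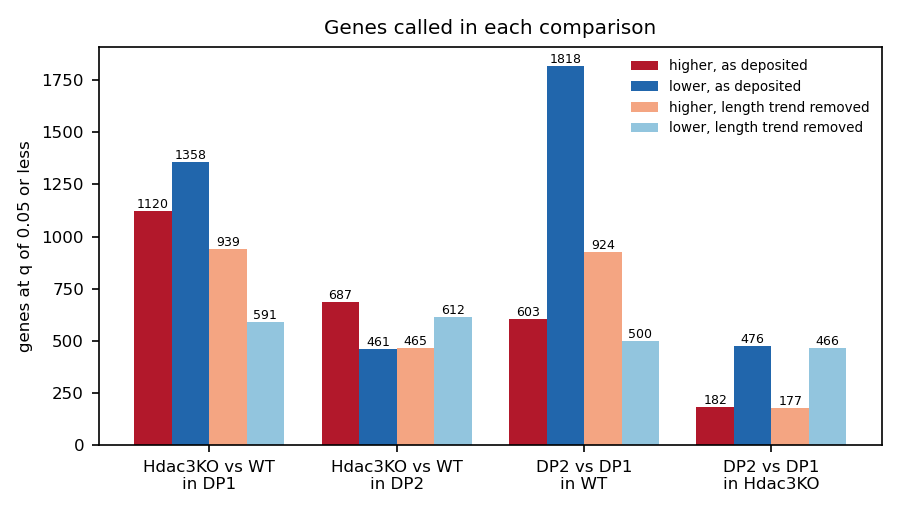
Bars give the number of genes at q of 0.05 or less in each of the 4 comparisons, higher and lower, as deposited (dark) and with the trend of fold change on transcript length removed (pale). In DP1, 1120 genes were higher and 1358 lower as deposited, and 939 and 591 with the trend removed, while the Hdac3KO stage comparison held 182 and 476 as deposited and 177 and 466 with it removed.

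Among the named genes that rose most in Hdac3KO DP1, H2-T3, which encodes a nonclassical MHC class I molecule, rose 19.6-fold from 1.003 to 19.7 FPKM in the authors' deposited table (4.29 ± 1.06, q = 0.000879). Tmprss4, a gene for a membrane serine protease, rose 15.0-fold from 0.547 to 8.19 FPKM in the authors' deposited table (3.90 ± 0.96, q = 0.000879). Il18r1, a receptor chain for interleukin-18, went from 0.308 to 5.11 FPKM in the authors' deposited table (4.05 ± 1.33, q = 0.0158). Cd53, a tetraspanin gene of leukocytes, rose 9.20-fold from 2.77 to 25.5 FPKM in the authors' deposited table (3.20 ± 0.79, q = 0.000879). Spsb1, which encodes an adaptor of ubiquitin ligases, rose from 2.67 to 25.9 FPKM, and the C-type lectin gene Cd302 from 0.597 to 7.59, in the authors' deposited table. Gimap4 (0.972 to 9.38 FPKM) and Gimap3 (0.625 to 5.52 FPKM) completed this group in the authors' deposited table, with log2 changes of 3.27 and 3.14. Rprl3, an RNA gene with near-identical copies in the genome, had a log2 change of 5.34 ± 1.32 in the authors' deposited table, and how its reads were divided among copies is not known.

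The named genes that fell most in Hdac3KO DP1 included the potassium channel genes Kcnk2, from 9.62 to 0.887 FPKM, and Kcnj14, from 9.51 to 1.07, in the authors' deposited table (-3.44 ± 0.85 and -3.15 ± 0.78). Rab6b, a gene for a GTPase of vesicle transport, fell from 8.53 to 1.20 FPKM, and Myzap from 16.7 to 2.62, in the authors' deposited table. Svip fell from 24.6 to 3.41 FPKM and Ndufs5, a subunit gene of mitochondrial complex I, from 48.7 to 7.14 in the authors' deposited table (-2.85 ± 0.70 and -2.77 ± 0.68). Klra5, a gene of the Ly49 receptors of NK cells, had a change of -2.95 ± 1.15 in the authors' deposited table (q = 0.0458), and its call ended with the length trend removed (-2.39, q = 0.15) or after centring (-2.83, q = 0.0575), where the change was about as large. The call of the ribosomal protein gene Rps27 (-4.90 ± 1.74, q = 0.0264 in the authors' deposited table) likewise ended with the length trend removed (-4.16, q = 0.0865). Xist, the RNA of the inactive X chromosome, was at 0.0945 FPKM in WT and 208 in Hdac3KO in the authors' deposited table, while the Y-linked Kdm5d was at 20.01 and 0.264. Erdr1, which lies on the sex chromosomes, was at 224 and 1.38 FPKM in the authors' deposited table. The Y-linked genes Uty, Ddx3y and Eif2s3y went the same way without passing (q = 0.426, 0.236 and 0.430 in the authors' deposited table).

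Part of the TCR-induced genes of positive selection were lower in Hdac3KO DP1, and part of the TCR pathway components were higher. Of 22 measured TCR-induced genes, 8 were lower and 1 was higher, 9 and 1 adjusted over the list alone, and 13 did not pass. The list median was -0.59, at a percentile of no more than 0.02 among 10000 random lists of like expression. At a minimum of 5 FPKM the median without centring went from -0.70 to -0.40, at a percentile of 5.2, inside the limits of random lists. Pdcd1, which encodes the inhibitory receptor PD-1, fell from 2.31 to 0.525 FPKM in the authors' deposited table (-2.14 ± 0.69, q = 0.0143). Id3, an inhibitor of E proteins, fell from 29.9 to 9.04 FPKM in the authors' deposited table (-1.73 ± 0.43), Itm2a from 19.5 to 6.35 and the early response gene Egr1 from 12.5 to 4.41. Cd53 was the only member that rose. CD5 and CD69 are surface markers of TCR signal strength. Their transcript changes did not pass, Cd5 at 58.9 and 55.0 FPKM (q = 0.818) and Cd69 at 9.82 and 17.0 (q = 0.101) in the authors' deposited table. Cells of both genotypes were sorted by surface CD5, which may by itself keep Cd5 alike. Of 28 TCR signalling genes, 10 were higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 0.51 and an excess of higher genes by Fisher's exact test (adjusted p = 0.0044). Themis, a gene needed for positive selection, rose from 283 to 862 FPKM in the authors' deposited table (1.61 ± 0.40). Dusp5 (20.1 to 51.8 FPKM) and Nfatc2 (4.52 to 8.97 FPKM) were also higher in the authors' deposited table, while Ptpn6, the gene of the phosphatase SHP-1, fell from 107 to 61.4.

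Genes of the DP stage and of later maturation were called in both directions in Hdac3KO DP1. Of 25 DP-stage genes, 7 were higher and 3 lower (8 and 3 adjusted over the list alone), with a median of 0.41, and the higher genes were not in excess by Fisher's exact test (adjusted p = 0.0826). Bcl6, a transcriptional repressor, rose from 40.4 to 111 FPKM in the authors' deposited table (1.46 ± 0.36), Spo11 from 18.6 to 57.1 and the fatty acid elongase gene Elovl6 from 1.30 to 4.21. Mns1 fell from 148 to 55.9 FPKM in the authors' deposited table, and Cd24a and Slc7a11 also fell. The recombinase genes Rag1 (1199 and 2655 FPKM, q = 0.191) and Rag2 (160 and 210 FPKM, q = 0.269) did not pass in the authors' deposited table. Of 22 post-selection maturation genes, 6 were higher and 1 lower (9 and 3 adjusted over the list alone). Their median was 0.67 (percentile 99.99), with no excess of higher genes by Fisher's exact test (adjusted p = 0.135). Gimap7 rose from 10.96 to 81.8 FPKM in the authors' deposited table (2.90 ± 0.72), and Ccr7, the chemokine receptor of cells bound for the medulla, from 1.31 to 5.07. H2-K1, a classical MHC class I gene, fell from 14.2 to 6.19 FPKM in the authors' deposited table. In the NF-kB list 6 of 16 targets were higher and 0 lower, also adjusted over the list alone, with a median of 0.45 and an excess by Fisher's exact test (adjusted p = 0.0364). At a minimum of 5 FPKM the median without centring went from 0.34 to 0.17 (percentile 88.4). With a pseudocount of 1 the percentile was 97.1, and both lay inside the limits. Il2ra, the interleukin-2 receptor α chain, rose from 3.49 to 19.6 FPKM in the authors' deposited table (2.49 ± 0.61), and the cytokine genes Tnf (1.55 to 4.36 FPKM) and Lta (0.612 to 2.32 FPKM) also rose.

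Genes of DNA replication, mitosis and chromatin assembly were lower in Hdac3KO DP1. In the S phase list 17 of 30 genes were lower and 0 higher (20 lower adjusted over the list alone), with a median of -0.63 and an excess by Fisher's exact test (adjusted p = 4.51e-07). With the length trend removed the median was also -0.63 and 8 were lower. Pcna, the replication clamp, fell from 927 to 442 FPKM in the authors' deposited table, and the helicase gene Mcm5 from 112 to 48.2. Among G2/M genes 13 of 30 were lower and 0 higher (15 lower adjusted over the list alone), with a median of -0.49, and with the length trend removed the median was -0.42 and 6 were lower. Nuf2, a kinetochore gene, fell from 74.7 to 32.9 FPKM, and the mitotic cyclin gene Ccnb1 from 124 to 55.0, in the authors' deposited table. Mki67, which encodes the Ki-67 antigen, did not pass (374 and 444 FPKM, q = 0.588 in the authors' deposited table). Replication-dependent histone genes, which are short and intronless, were lower in 25 of 28 cases and higher in 0 (26 lower adjusted over the list alone), with a median of -0.95. With the length trend removed that median was -0.37 and 3 were lower, and reads shared among near-identical copies cannot be separated at gene level. Hist1h1e fell from 694 to 252 FPKM and Hist1h3c from 567 to 220.1 in the authors' deposited table. Housekeeping genes were lower in 11 of 18 cases and higher in 0 (12 lower adjusted over the list alone), with a median of -0.69, and with the length trend removed the median was -0.37 and 1 was lower.

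Genes of cell death and survival went both ways in Hdac3KO DP1. Of 21 such genes 3 were higher and 7 lower, also adjusted over the list alone, with a median of 0.23, and with the length trend removed 2 were higher and 1 lower. Mcl1, a survival gene of the BCL2 family, rose from 74.8 to 158 FPKM in the authors' deposited table (1.08 ± 0.27), while the death-promoting Bmf fell from 17.8 to 8.41. Targets of p53 were higher in 5 and lower in 3 of 20 cases, also adjusted over the list alone (median 0.34), and Trp53inp1 rose from 367 to 853 FPKM in the authors' deposited table. CD4 lineage genes gave 1 higher and 1 lower of 16 (median 0.28), and CD8 lineage and cytotoxic genes 0 and 1 of 9 (median -0.05), the same adjusted over the list alone. The higher CD4 lineage gene was Runx1 and the lower CD8 lineage gene Gzma. Interferon-stimulated genes gave 2 higher and 1 lower of 20 (median 0.25), cholesterol synthesis genes 1 and 3 of 23 (median -0.27), and lipid handling genes of the nuclear receptor LXR 3 and 2 of 18 (median -0.05), the same adjusted over the list alone. Relative to the median gene the cholesterol split turned to 3 higher and 2 lower, and with the length trend removed that of the LXR list turned to 1 and 2. Pmvk, a kinase gene of the mevalonate pathway, fell from 75.1 to 26.9 FPKM in the authors' deposited table (-1.48 ± 0.37). Glycolysis and hypoxia genes gave 1 higher and 5 lower of 20 (1 and 6 adjusted over the list alone, median -0.25), and 1 and 2 with the length trend removed. Purinergic genes gave 0 higher and 1 lower of 8, which was Adk (median -0.08), and chemokine and homing receptors 3 and 0 of 14 (median 0.46), both also adjusted over the list alone. Sialyl- and glycosyltransferase genes gave 3 higher and 0 lower of 13 (4 and 1 adjusted over the list alone, median 0.40), with St6gal1 rising from 8.27 to 26.4 FPKM in the authors' deposited table.

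Markers of other thymic cells gave list medians inside the limits of random lists in Hdac3KO DP1, at 0.07 for double-negative stage, -0.03 for regulatory T cell, 0.43 for γδ T and NK, 0.39 for myeloid and 0.24 for epithelium markers. Among 7 double-negative stage markers Hhex, a homeobox gene, fell from 47.8 to 8.53 FPKM in the authors' deposited table and Il2ra rose. The 4 regulatory T cell markers gave 1 higher (Il2ra) and 1 lower, Ikzf2, and Itgam, the CD11b gene of myeloid cells, was the 1 higher gene of 3 myeloid markers at 2.40 and 9.58 FPKM in the authors' deposited table. Of 2 erythroid markers Alas2 was higher (0.676 and 2.51 FPKM), and of 4 thymic epithelium markers Psmb11 (3.21 and 7.30 FPKM), in the authors' deposited table, each list with 1 higher and 1 lower adjusted over the list alone. None of the 3 γδ T and NK markers and not the 1 measured B cell marker was called, and the counts of these, the double-negative, regulatory and myeloid markers were the same adjusted over the list alone.

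In DP2 cells the same comparison of genotypes, with the same limit from sex, asked which genes differ once TCR signalling had begun. Genes that TCR signals induce were lower in Hdac3KO, among them Pdcd1, Nr4a3, Itm2a and Id2. Genes typical of the DP stage, such as Rag2, Bcl6 and Cd8b1, were higher, and the genes of mitosis were lower. Il7r and Bcl2, a cytokine receptor and a survival factor of selected thymocytes, were also lower. The authors' deposited table held 687 higher and 461 lower genes, 10.8% of the 10674 tested, with at least a 2-fold difference in 351 and 355. The median gene lay at 0.12, and relative to it 463 genes were higher and 613 lower, so here too the direction of the majority depended on the scaling.

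Of the named genes that rose most in Hdac3KO DP2, Tmprss4 rose 25.3-fold from 0.459 to 11.6 FPKM in the authors' deposited table (4.66 ± 1.15, q = 0.00134). Il18r1 went from 0.744 to 12.5 FPKM in the authors' deposited table (4.07 ± 1.005, q = 0.00134), and H2-T3 from 0.787 to 13.1 (4.05 ± 1.07, q = 0.00338). Spsb1 rose 11.6-fold from 4.50 to 52.3 FPKM in the authors' deposited table (3.54 ± 0.87, q = 0.00134). Itgam rose from 1.60 to 15.7 FPKM and Cldn4, a claudin gene of tight junctions, from 2.58 to 19.2, in the authors' deposited table (3.29 ± 0.81 and 2.90 ± 0.71). The lipid receptor gene Gpr55 (0.677 to 5.11 FPKM) and the locus C85492 (1.12 to 9.77 FPKM) were the remaining members of this group in the authors' deposited table, besides Rprl3 (6.76 ± 1.995, q = 0.0114). Xist was at 0.243 FPKM in WT and 139 in Hdac3KO in the authors' deposited table, Ddx3y at 156 and 0.693, Kdm5d at 34.6 and 0.322, and Erdr1 at 218 and 0.560. Uty was at 62.6 FPKM in WT and is listed at 0 in Hdac3KO in the authors' deposited table.

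Of the named genes that fell most in Hdac3KO DP2, Pdcd1 fell 15.7-fold from 20.7 to 1.32 FPKM in the authors' deposited table (-3.97 ± 0.98, q = 0.00134). Il7r, the interleukin-7 receptor α chain, fell from 10.2 to 0.653 FPKM in the authors' deposited table (-3.96 ± 1.21, q = 0.0159). Folr4, a folate receptor gene of regulatory T cells, fell from 10.2 to 0.476 FPKM in the authors' deposited table (-4.43 ± 1.24, q = 0.00666). Kcnj14 fell from 23.9 to 1.57 FPKM and Prkg2, a cGMP-dependent kinase gene, from 7.14 to 0.606, in the authors' deposited table (-3.93 ± 0.97 and -3.56 ± 0.88). Hhex fell from 221 to 21.3 FPKM in the authors' deposited table (-3.37 ± 0.83, q = 0.00134), and the zinc finger gene Zfp248 from 249 to 17.6 (-3.82 ± 0.94).

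Of 23 measured TCR-induced genes in Hdac3KO DP2, 12 were lower and 0 higher (14 lower adjusted over the list alone). Their median was -1.08, below all 10000 random lists, with an excess by Fisher's exact test (adjusted p = 8.98e-10). The regulatory T cell and myeloid marker lists were low too, and Ikzf2 belongs to both the TCR-induced and the regulatory T cell list. Nr4a3, an orphan nuclear receptor gene, fell from 21.3 to 4.66 FPKM in the authors' deposited table (-2.19 ± 0.54), and Itm2a from 360.2 to 84.0 (-2.10 ± 0.52). Id2 fell from 23.1 to 5.72 FPKM, Egr2 from 19.3 to 5.36 and Egr1 from 60.2 to 26.3 in the authors' deposited table. Cd5 (274 and 232 FPKM, q = 0.612) and Cd69 (156 and 113 FPKM, q = 0.224) did not pass in the authors' deposited table. For Cd5 the sorting by surface CD5 limits this comparison, as in DP1. TCR signalling genes gave 6 higher and 1 lower of 29 (9 and 1 adjusted over the list alone, median 0.24). The adaptor gene Grap2 rose from 73.2 to 179 FPKM in the authors' deposited table, while Spry1, an inhibitor of kinase signalling, fell from 2.28 to 0.271.

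**Figure D2:**
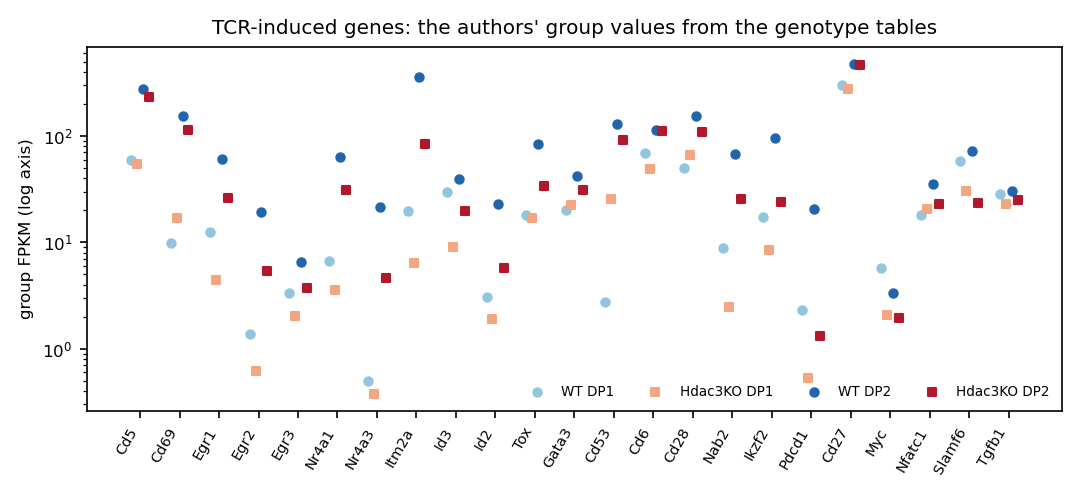
Points give the group FPKM (log axis) of the TCR-induced genes in WT and Hdac3KO DP1 and DP2 cells, from the authors' deposited tables of genotype, each normalized separately, with values of 0 not drawn. Pdcd1 reached 20.7 FPKM in WT DP2 and 1.32 in Hdac3KO DP2, while Cd5, whose protein was used to sort the cells, was at 274 and 232.

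DP-stage genes were higher in 13 and lower in 1 of 25 cases in Hdac3KO DP2 (13 and 2 adjusted over the list alone). The list median was 0.67, above all 10000 random lists, with an excess by Fisher's exact test (adjusted p = 1.37e-08). Ets2 rose from 120.1 to 357 FPKM in the authors' deposited table (1.57 ± 0.39), Bcl6 from 48.8 to 118 and Plxnd1, a guidance receptor gene of thymocytes, from 41.2 to 98.6. In the authors' deposited table Rag2 rose from 95.9 to 201 FPKM, and Rag1, at 671 and 3006 FPKM, did not pass (q = 0.328). The coreceptor genes Cd8b1 (639 and 1383 FPKM) and Cd4 (208 and 392) were higher in the authors' deposited table, but Cd8a was not called. Post-selection maturation genes gave 9 higher and 3 lower of 22 (10 and 3 adjusted over the list alone), with an excess of higher genes by Fisher's exact test (adjusted p = 4.69e-05) and a median of 0.19, inside the limits of random lists. Gimap7 rose from 35.0 to 229 FPKM in the authors' deposited table (2.71 ± 0.67) and Gimap4 from 21.8 to 97.7. Bcl2 fell from 15.8 to 4.65 FPKM in the authors' deposited table (-1.76 ± 0.43), and Ms4a6b was the other lower gene besides Il7r. In the Gimap family, examined after the values were seen, 7 of 8 measured genes were higher, against 5 of 8 in DP1.

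CD4 lineage genes were lower in 4 and higher in 1 of 17 cases in Hdac3KO DP2, also adjusted over the list alone (median 0.03, Fisher's exact test for lower genes, adjusted p = 0.0365). Cd40lg, a ligand of helper T cells, fell from 24.7 to 3.60 FPKM in the authors' deposited table (-2.78 ± 0.71), Tox, a factor of the CD4 lineage, from 84.3 to 33.8, and Lef1 from 144 to 69.8. CD8 lineage and cytotoxic genes gave 3 higher and 0 lower of 10 (4 and 3 adjusted over the list alone, median 0.02), with the perforin gene Prf1 at 2.17 and 5.94 FPKM in the authors' deposited table. Survival and apoptosis genes gave 3 higher and 1 lower of 20, also adjusted over the list alone (median 0.31). Bcl2l1, which encodes BCL-XL, rose from 37.9 to 81.0 FPKM in the authors' deposited table (1.09 ± 0.27), as did the death-promoting p53 target Bbc3, from 6.86 to 14.4. Targets of p53 gave 4 higher and 1 lower of 20 (5 and 1 adjusted over the list alone, median 0.23). Trp53inp1 rose from 501 to 1297 FPKM and Perp fell from 66.0 to 23.1 in the authors' deposited table. In the NF-kB list 4 targets were higher and 2 lower of 20, also adjusted over the list alone (median 0.25), with Tnf at 3.11 and 12.5 FPKM and Tnfrsf9, the 4-1BB costimulatory receptor gene, at 3.84 and 0.660 in the authors' deposited table.

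Genes of mitosis were lower in Hdac3KO DP2 in 18 of 30 cases and higher in 0 (23 lower adjusted over the list alone). Their median was -1.19, with an excess by Fisher's exact test (adjusted p = 5.93e-16). Fold changes in this comparison followed the GC content of transcripts (Spearman rho 0.32 across genes), with a rho on length of 0.02, or 0.12 given GC. With the GC trend removed, an alternative chosen after the data had been seen, the G2/M median was -1.16. Mki67 fell from 251 to 98.7 FPKM in the authors' deposited table (-1.35 ± 0.33), Nuf2 from 28.9 to 8.74 and Ndc80, another kinetochore gene, from 43.4 to 15.1. S phase genes were lower in 10 of 30 cases and higher in 0 (12 lower adjusted over the list alone, median -0.72), and Rrm2, a ribonucleotide reductase gene, fell from 83.2 to 32.0 FPKM in the authors' deposited table. Replication-dependent histones gave 1 higher and 3 lower of 27 (median -0.47) and housekeeping genes 1 and 0 of 18 (median -0.17), the same adjusted over the list alone. Interferon-stimulated genes gave 1 higher and 2 lower of 21 (median 0.05) and cholesterol synthesis genes 3 and 1 of 22 (median 0.05), the same adjusted over the list alone. Pmvk fell from 289 to 59.1 FPKM and Mvd, a decarboxylase gene of the same pathway, rose from 1.98 to 9.44, in the authors' deposited table. The LXR list gave 3 higher and 0 lower of 18 (4 and 1 adjusted over the list alone, median 0.17), with the sterol transporter gene Abcg1 rising from 24.3 to 73.7 FPKM in the authors' deposited table. Glycolysis and hypoxia genes gave 2 higher and 1 lower of 21, also adjusted over the list alone (median -0.00), or 0 and 1 relative to the median gene, and purinergic genes 1 and 0 of 10 (3 and 2 adjusted over the list alone, median -0.67), the higher one being Ada. The purinergic median turned from -0.56 without centring to 0.00227 at a minimum of 5 FPKM, so its direction depended on that minimum. Sialyl- and glycosyltransferase genes gave 2 higher and 3 lower of 14 (4 and 3 adjusted over the list alone, median -0.03), among them St3gal6 (5.70 to 17.6 FPKM) and St3gal2 (10.9 to 4.08 FPKM) in the authors' deposited table. Chemokine and homing receptors gave 3 higher and 2 lower of 16 (4 and 3 adjusted over the list alone, median -0.08). Selplg, which encodes the selectin ligand PSGL-1, rose from 44.7 to 149 FPKM in the authors' deposited table, while the adhesion receptor gene Cd44 fell from 4.37 to 0.721.

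Among markers of other cells in Hdac3KO DP2, the regulatory T cell and myeloid lists had medians of -0.83 and -0.94, at percentiles of 0.65 and 1.57 among random lists and so below the limit of 2.5. The medians of the double-negative stage (0.37), γδ T and NK (0.74) and epithelium (0.12) markers lay inside the limits. Of 8 double-negative stage markers 2 were higher (Il2ra and Notch3) and 3 lower (Il7r, Hhex and Cd44), or 3 and 3 adjusted over the list alone. Regulatory T cell markers gave 1 higher and 2 lower of 6, also adjusted over the list alone, with Ikzf2, which encodes Helios, falling from 94.8 to 24.0 FPKM in the authors' deposited table. Of 3 γδ T and NK markers 2 were higher, also adjusted over the list alone, and Il17re among them was at 1.33 and 3.42 FPKM in the authors' deposited table. Among 4 myeloid markers Itgam was higher and H2-Ab1, an MHC class II gene, fell from 5.41 to 1.15 FPKM in the authors' deposited table (1 and 2 adjusted over the list alone). The B cell marker, 2 erythroid and 4 epithelium markers gave 0 calls, also adjusted over the list alone. Interleukin receptor genes, a family examined after the values were seen, were higher in 9 and lower in 3 of 23 cases, and Il21r, Il4ra and Il10ra were among the higher ones.

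Setting the genotype effects of DP1 and DP2 side by side asked whether Hdac3 loss acts on the same genes at both points, and these tables share no libraries. Across 10142 genes the log2 changes correlated with a Spearman rho of 0.40 and a Pearson r of 0.50, where genes are not independent replicates. Genes higher at both points numbered 281, against 73.0 if the lists were independent, and 180 were lower at both points, against 49.7. Only 9 genes were called in opposite directions. Both comparisons carry the same difference in Xist and Y-linked genes, so genes that follow sex could recur at both points too. The counts for independent lists do not separate this from Hdac3 loss. Tmprss4, Il18r1, H2-T3 and Spsb1 were among the genes higher at both points, and Kcnj14, Pdcd1 and Hhex among those lower at both.

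**Figure D3:**
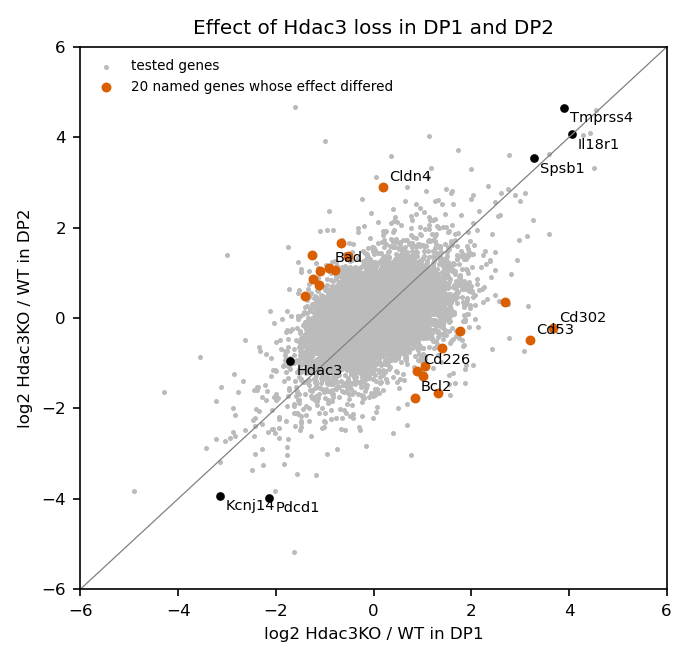
Each point is 1 gene, with its log2 Hdac3KO over WT change in DP1 on the horizontal and in DP2 on the vertical axis, and orange marks 20 named genes whose effects differed. Tmprss4, Il18r1 and Spsb1 lie at the upper right and Kcnj14 and Pdcd1 at the lower left, while Cd53 (3.20 and -0.49) and Bcl2 (0.84 and -1.76) lie far from the diagonal; genes beyond 6 on either axis fall outside the plot.

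Whether the effect of Hdac3 loss itself differed between DP1 and DP2 was tested as the difference of both log2 changes, with calls that depended on the settings. No exact test is possible with 1 value per group, so this is a normal test, and its q is the Benjamini-Hochberg adjusted p. By this test the Hdac3 effect was higher in DP2 for 91 genes and lower for 120, of 10144 tested. Relative to the median genes the split was 34 and 333, with the length trend removed 8 and 98, and with the GC trend removed 13 and 71. Standard errors from the deposited statistic gave 134 and 399, and with the SE multiplied by 1.5 this test gave 0 calls, with 413 at an unadjusted p of 0.05. Cd53 rose in DP1 (3.20) and not in DP2 (-0.49), a difference of -3.69 ± 0.83 (95% interval -5.31 to -2.07, q = 0.00894). Bcl2 was at 0.84 in DP1 and -1.76 in DP2, a difference of -2.60 ± 0.59 (95% interval -3.77 to -1.44, q = 0.00894). Cd302 differed by -3.90 ± 1.18 (q = 0.0487). All of these calls also passed with the length trend removed. Bad, a death-promoting partner of BCL2, differed by 2.02 and Cldn4 by 2.71 in the other direction, and of the 10 named genes with the largest rise only Shfm1 still passed with the length trend removed. Within the survival list there were 3 higher (Bad, Bcl2l1 and Bmf) and 1 lower difference (Bcl2) among 20 genes, or 5 and 2 adjusted over the list alone. With the length trend removed the differences of Bad (1.44, q = 0.247) and Bcl2l1 (0.87, q = 0.281) did not pass, and the list median went from 0.10 to -0.03. TCR-induced genes gave 0 higher and 1 lower of 22 (0 and 4 adjusted over the list alone), with a list median of -0.76. Pdcd1 (-1.84, q = 0.406), Egr1 (0.31, q = 0.779), Itm2a (-0.48, q = 0.742) and Rag2 (0.68, q = 0.2996) did not pass, so their effects were not shown to differ. G2/M genes gave 0 higher and 3 lower of 30, Cenpe, Cenpf and Mki67 (0 and 4 adjusted over the list alone), but by the stage tables, the other route to this difference, 0 of 30 passed.

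The change from DP1 to DP2 in WT cells was measured to describe the normal course of the stage. Genes that TCR signals induce, such as Cd69, Nr4a1 and Egr2, were higher in DP2. So were genes of later maturation, such as Il7r, Bcl2 and Gimap4. Cd5 was higher too, but the populations were sorted by surface CD5, so its rise may follow the sorting. Genes of DNA replication and mitosis were lower. Some genes of the early DP stage, such as Rag2, Ptcra and Dntt, were lower as well, while the DP-stage list median lay inside the limits of random lists. As the authors' deposited table gives it, 603 genes were higher and 1818 lower, 22.3% of the 10851 tested, and 443 and 1159 of them differed at least 2-fold. The median gene lay at -0.33, relative to which 1177 were higher and 705 lower, and with the length trend removed the counts were 924 and 500, so the direction of the majority depended on the scaling.

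Among the named genes that rose most in WT, Cd53 rose 40.9-fold from 3.11 to 127 FPKM in the authors' deposited table (5.36 ± 1.32, q = 0.000835). Nr4a3 rose 35.7-fold from 0.564 to 20.2 FPKM in the authors' deposited table (5.16 ± 1.27, q = 0.000835). Il7r went from 0.253 to 9.88 FPKM in the authors' deposited table (5.29 ± 2.01, q = 0.0417; 5.18, q = 0.0663 with the GC trend removed), and Btla, an inhibitory receptor gene, from 0.556 to 18.4 (5.05 ± 1.80, q = 0.0282). Itm2a rose 15.9-fold from 21.997 to 350.4 FPKM in the authors' deposited table (3.99 ± 0.98, q = 0.000835). Chl1, an adhesion gene, rose from 0.123 to 7.53 FPKM, Folr4 from 0.617 to 9.72 and the kinase gene Stk39 from 0.393 to 5.70 in the authors' deposited table. Gimap4 (1.10 to 20.8 FPKM) and Gimap3 (0.705 to 10.2 FPKM) completed this group in the authors' deposited table. Among the named genes that fell, Fads2, a fatty acid desaturase gene, went from 13.3 to 1.67 FPKM in the authors' deposited table (-2.998 ± 0.74, q = 0.000835). The centromere gene Cenpm fell from 16.7 to 2.24 FPKM, the ubiquitin ligase gene Traip from 10.4 to 1.37 and the olfactory receptor gene Olfr571 from 9.23 to 1.08 in the authors' deposited table. The rest were histone genes, Hist1h4d at 2329.95 and 302 FPKM, Hist2h2bb, Hist1h4b, Hist1h2af, Hist1h3b and Hist2h3b, with log2 changes from -3.24 to -2.85 in the authors' deposited table. The calls of Hist1h3b (-2.21, q = 0.109) and Hist2h3b (-1.97, q = 0.0552) ended with the length trend removed.

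TCR-induced genes were higher in 16 and lower in 1 of 23 cases in WT, also adjusted over the list alone, with a median of 2.32 above all 10000 random lists (Fisher's exact test, adjusted p = 2.17e-14). The regulatory T cell and myeloid marker lists had high medians as well (1.48 and 1.53). Cd69 rose from 11.05 to 152 FPKM in the authors' deposited table (3.78 ± 0.93) and Cd5 from 67.2 to 262 (1.96 ± 0.48). Nr4a1 rose from 7.58 to 59.8 FPKM, Egr2 from 1.55 to 18.4 and Pdcd1 from 2.63 to 19.8 in the authors' deposited table, while Myc fell. DP-stage genes were lower in 11 of 24 cases and higher in 0 (13 lower adjusted over the list alone, median -0.50). That median lay inside the limits of random lists, also with the GC trend removed (percentile 7.06). It lay below them with the length trend removed (percentile 0.28). With the length trend removed the median was also -0.50 and 4 were lower, and relative to the median gene 4 were lower and 1 higher. Ptcra, the pre-TCR α chain, fell from 41.6 to 10.4 FPKM in the authors' deposited table (-1.99 ± 0.49), Dntt, the terminal transferase gene, from 2195 to 783, and Rag2 from 181 to 93.2. Rag1 did not pass, at 1353 and 648 FPKM in the authors' deposited table (q = 0.202). Post-selection maturation genes were higher in 10 and lower in 1 of 23 cases (11 and 1 adjusted over the list alone, median 1.09), with Bcl2 at 2.34 and 15.0 FPKM in the authors' deposited table. TCR signalling genes gave 5 higher and 2 lower of 29 (7 and 2 adjusted over the list alone, median 0.37), 9 and 0 relative to the median gene and 7 and 0 with the length trend removed, and the Src kinase gene Fyn rose from 19.0 to 40.2 FPKM in the authors' deposited table. Among NF-kB targets 7 of 19 were higher and 0 lower (8 higher adjusted over the list alone, median 0.87), and Relb rose from 1.34 to 5.29 FPKM in the authors' deposited table. Of the CD4 lineage genes 4 were higher and 2 lower of 18, also adjusted over the list alone (median 0.44), Tox rising from 20.3 to 80.7 FPKM and Cd4 falling from 409 to 198 in the authors' deposited table. CD8 lineage and cytotoxic genes gave 2 higher and 2 lower of 11 (3 and 3 adjusted over the list alone, median 0.59), with the granzyme gene Gzma at 74.5 and 19.7 FPKM in the authors' deposited table. Relative to the median gene the CD4 list gave 3 and 0 and the CD8 list 4 and 1, and with the length trend removed both gave 4 and 0.

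Genes of the cell cycle fell from DP1 to DP2 in WT. S phase genes were lower in 28 of 30 cases and higher in 0 (29 lower adjusted over the list alone), with a median of -1.67, and with the length trend removed the median was also -1.67 and 23 were lower. Mcm10 fell from 37.8 to 5.40 FPKM and Cdc6, which loads the replicative helicase, from 29.7 to 4.70, in the authors' deposited table (-2.81 ± 0.69 and -2.66 ± 0.66). G2/M genes were lower in 24 of 30 cases and higher in 0 (26 lower adjusted over the list alone), with a median of -1.27 and 18 lower both relative to the median gene and with the length trend removed, and Aurkb, a mitotic kinase gene, fell from 43.4 to 8.14 FPKM in the authors' deposited table. Replication-dependent histones were lower in 27 of 28 cases and higher in 0 (28 lower adjusted over the list alone, median -1.95), and 9 were lower with the length trend removed (median -1.48). Housekeeping genes were lower in 8 of 18 cases and higher in 0 (11 lower adjusted over the list alone, median -0.41), and with the length trend removed 0 were lower and 1 was higher (median -0.35).

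Genes of sterol synthesis were also lower in WT DP2, in 11 of 22 cases, with 1 higher (13 and 1 adjusted over the list alone, median -0.57), and in 5 with the length trend removed, where the median was -0.59. Idi1, an isomerase gene of this pathway, fell from 28.8 to 9.03 FPKM in the authors' deposited table (-1.67 ± 0.41), while Pmvk rose from 85.7 to 273. The LXR list gave 0 higher and 4 lower of 17, also adjusted over the list alone (median -0.30), among them Acaca and Fads1. Survival and apoptosis genes gave 2 higher and 7 lower of 21 (2 and 9 adjusted over the list alone, median -0.03), 4 and 4 relative to the median gene, and 4 and 2 with the length trend removed. Bcl2l1 fell from 105 to 35.9 FPKM in the authors' deposited table (-1.54 ± 0.38), and Bad from 13.5 to 3.83. Targets of p53 gave 1 higher (Perp) and 1 lower (Rps27l) of 21 (median 0.33), and histone deacetylases and corepressors 0 and 1 of 18, Hdac1 (median 0.02), both also adjusted over the list alone. Interferon-stimulated genes gave 2 higher and 1 lower of 22 (1 and 1 adjusted over the list alone, median 0.59), with Bst2, the tetherin gene, at 18.4 and 3.82 FPKM in the authors' deposited table. Glycolysis and hypoxia genes gave 1 higher and 7 lower of 20 (1 and 9 adjusted over the list alone, median -0.06), 2 and 1 relative to the median gene, and 1 and 1 with the length trend removed. Purinergic genes gave 1 higher and 4 lower of 10 (2 and 4 adjusted over the list alone, median -0.20), with P2rx7, an ATP-gated channel gene, rising from 0.459 to 5.57 FPKM in the authors' deposited table. Relative to the median gene 2 purinergic genes were higher and 2 lower, and with the length trend removed 3 and 1. Sialyl- and glycosyltransferase genes gave 4 higher and 0 lower of 14 (4 and 1 adjusted over the list alone, median 0.51), and St6gal1 rose from 9.40 to 40.6 FPKM in the authors' deposited table. Chemokine and homing receptors gave 2 higher and 2 lower of 15 (4 and 2 adjusted over the list alone, median 0.94), or 7 and 1 relative to the median gene, with Ccr4 rising from 4.72 to 62.0 FPKM in the authors' deposited table.

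Marker lists in WT had medians of -0.99 for double-negative stage, 1.48 for regulatory T cell and 1.53 for myeloid markers, at percentiles of 0.02, 99.99 and 99.2 among random lists. The medians of γδ T and NK (-0.46) and epithelium markers (0.57) lay inside the limits of random lists. Double-negative stage markers gave 2 higher and 5 lower of 9 in WT (3 and 5 adjusted over the list alone), Notch3 falling from 6.38 to 1.43 FPKM and Hhex rising from 54.8 to 208 in the authors' deposited table. Regulatory T cell markers gave 2 higher (Folr4 and Ikzf2) and 0 lower of 6, and γδ T and NK markers 0 and 2 of 3, both also adjusted over the list alone. Cd74, the invariant chain gene of antigen-presenting cells, was the 1 higher of 6 myeloid markers at 1.59 and 6.35 FPKM, and Epcam the 1 lower of 4 epithelium markers, in the authors' deposited table. The lower γδ T and NK and epithelium markers were not called relative to the median gene or with the length trend removed. The B cell and 2 erythroid markers gave 0 calls, and all of these counts were the same adjusted over the list alone.

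**Figure D4:**
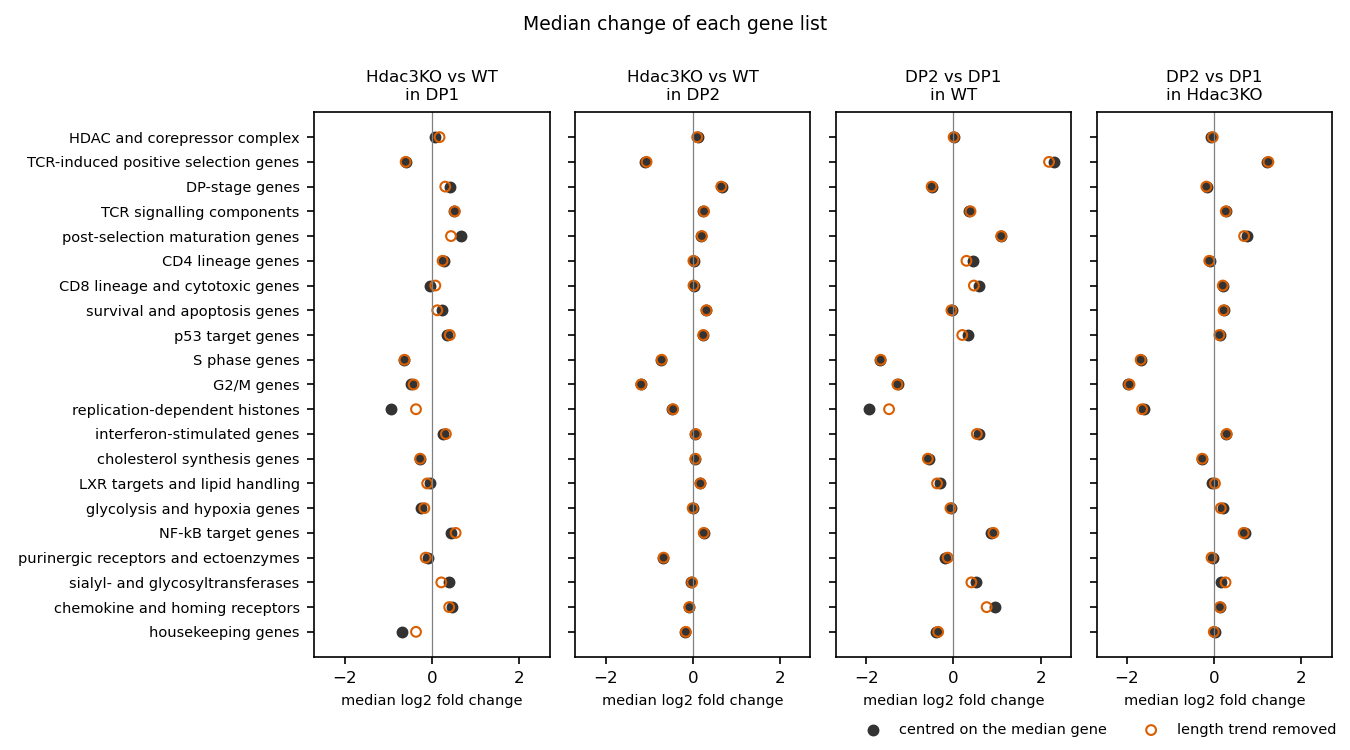
Points give the median log2 fold change of 21 gene lists in each of the 4 comparisons, centred on the median gene (filled) and with the trend on transcript length removed (open). TCR-induced genes lie at -0.59 and -1.08 in the genotype comparisons and at 2.32 and 1.21 in the stage comparisons, and histones move from -0.95 to -0.37 in DP1 when the trend is removed.

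In Hdac3KO cells the change from DP1 to DP2 asked how much of this course remains without Hdac3. The fall of cell cycle genes and the rise of TCR-induced genes such as Cd69, Egr1 and Nr4a1 were present. Cd5 rose too, but the populations were sorted by surface CD5, so its rise may follow the sorting. Values of the DP-stage gene Rag2 and of the survival gene Bcl2 did not pass. The authors' deposited table held 182 higher and 476 lower genes, 6.43% of the 10231 tested, with at least a 2-fold difference in 103 and 328.

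Of the named genes that rose most in Hdac3KO, Itm2a rose from 6.40 to 76.4 FPKM in the authors' deposited table (3.58 ± 0.88, q = 0.00151). Nr4a1 rose from 3.56 to 28.4 FPKM and Egr1 from 4.39 to 23.8 in the authors' deposited table (2.99 ± 0.74 and 2.44 ± 0.60). Nab2, a corepressor gene of the EGR factors, rose from 2.47 to 23.2 FPKM in the authors' deposited table (3.23 ± 0.95, q = 0.0147). Cd69 rose 5.98-fold from 17.1 to 103 FPKM in the authors' deposited table (2.58 ± 0.64, q = 0.00151). Gimap4 rose from 9.36 to 88.8 FPKM, Gimap3 from 5.52 to 33.8 and the chemokine receptor gene Ccr4 from 8.11 to 44.7 in the authors' deposited table. The epoxide hydrolase gene Ephx1 (0.610 to 6.04 FPKM) and the p38 kinase gene Mapk11 (1.80 to 9.69 FPKM) completed this group in the authors' deposited table. All named genes that fell most, except Fads2 (7.18 to 1.001 FPKM), belong to replication, repair or mitosis. Ccne2, which encodes cyclin E2, fell from 56.0 to 6.95 FPKM in the authors' deposited table (-3.01 ± 0.74), and Mcm10, Cenpk, Cenpm, E2f8, Kntc1, Neil3, Ckap2l and Rad54b fell by 2.71 to 3.22 on the log2 scale.

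TCR-induced genes were higher in 12 and lower in 0 of 22 cases in Hdac3KO (16 and 1 adjusted over the list alone), with a median of 1.21 above all 10000 random lists (Fisher's exact test, adjusted p = 5.41e-15). Cd5 rose from 54.8 to 210.0 FPKM in the authors' deposited table (1.94 ± 0.48), and Egr2 from 0.611 to 4.86. Post-selection maturation genes gave 10 higher and 1 lower of 21 (13 and 2 adjusted over the list alone, median 0.76), while Bcl2, at 3.67 and 4.22 FPKM, did not pass in the authors' deposited table (q = 0.865). DP-stage genes gave 0 higher and 2 lower of 25 (1 and 3 adjusted over the list alone, median -0.17), the cystine transporter gene Slc7a11 and Ptcra, with Rag2 at 211 and 182 FPKM in the authors' deposited table (q = 0.744). TCR signalling genes gave 3 higher and 0 lower of 28 (4 and 0 adjusted over the list alone, median 0.27), Dusp5, Ptpn6 and Prkcq. Among NF-kB targets 6 were higher and 0 lower of 18 (9 and 0 adjusted over the list alone, median 0.71), and Relb rose from 0.2996 to 3.62 FPKM in the authors' deposited table. Survival and apoptosis genes gave 3 higher and 1 lower of 20 (4 and 2 adjusted over the list alone, median 0.21). Bcl2l11, which encodes the death-promoting BIM, was among the higher ones (0.996 ± 0.25). CD4 lineage genes gave 2 higher (Id3 and Tox) and 1 lower (Runx1) of 16, also adjusted over the list alone (median -0.11), and CD8 lineage and cytotoxic genes 2 and 1 of 8 (3 and 1 adjusted over the list alone, median 0.20).

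Cell cycle genes fell in Hdac3KO, with S phase genes lower in 27 of 30 cases (28 adjusted over the list alone, median -1.68) and G2/M genes in 28 of 30 (30 adjusted over the list alone, median -1.97), and 0 higher in either list. Mki67 fell from 447 to 89.7 FPKM in the authors' deposited table (-2.32 ± 0.57). Replication-dependent histones were lower in 26 of 28 cases and higher in 0 (27 lower adjusted over the list alone, median -1.61). Cholesterol synthesis genes gave 1 higher and 3 lower of 23 (1 and 6 adjusted over the list alone, median -0.28), and the LXR list 0 and 3 of 17, also adjusted over the list alone (median -0.05). Glycolysis and hypoxia genes gave 4 higher and 1 lower of 20, also adjusted over the list alone (median 0.19), with Ankrd37 rising from 2.56 to 8.87 FPKM in the authors' deposited table. Chemokine and homing receptors gave 2 higher and 1 lower of 13 (4 and 1 adjusted over the list alone, median 0.14), sialyl- and glycosyltransferases 1 and 0 of 13 (St6gal1, median 0.15), and p53 targets 1 and 0 of 20 (Perp, median 0.13). Interferon-stimulated genes gave 0 higher and 1 lower of 20 (Ifit2, median 0.27) and housekeeping genes 0 and 1 of 18 (Hprt, median 0.01), and the 19 histone deacetylases and corepressors and 9 purinergic genes gave 0 calls. Those counts were the same adjusted over the list alone, as were those for transferases and p53 targets. Double-negative stage markers gave 1 higher (Hhex) and 4 lower (Dtx1, Ptcra, Notch3 and Notch1) of 6, and regulatory T cell markers 1 and 0 of 4 (Ikzf2), both also adjusted over the list alone. The γδ T and NK, B cell, erythroid, epithelium and myeloid markers gave 0 calls, with 1 higher myeloid marker adjusted over the list alone. The list medians were -0.70 for double-negative stage markers, at a percentile of 0.04 among random lists, and 0.25 for regulatory T cell, -0.10 for γδ T and NK, 0.57 for myeloid and 0.11 for epithelium markers, inside the limits.

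Across the genotypes, which share no libraries in these tables, the stage changes of 9965 genes correlated with a Spearman rho of 0.26 and a Pearson r of 0.44, where genes are not independent replicates. Genes higher in both numbered 106, against 8.54 if the lists were independent, and 355 were lower in both, against 84.0. Opposite calls were made for 8 genes. Among the genes whose DP1 to DP2 change differs between genotypes by the normal test of the difference, 206 had a higher and 106 a lower value in Hdac3KO, of 9969 tested. The split was 24 and 347 relative to the median genes, and 11 and 122 with the length trend removed. Because both tests use the same 4 groups, this one is another route to the interaction above. Both routes called 162 genes, all in the same direction. Bcl2 changed by 2.68 from DP1 to DP2 in WT and by 0.20 in Hdac3KO, a difference of -2.49 ± 0.73 (q = 0.0399) that did not pass with the length trend removed (q = 0.0691). Cd302 differed by -3.79 ± 0.97 (q = 0.0175). For Cd53 the difference by this route was -3.65 (q = 0.104). TCR-induced genes gave 0 calls by this route, with a list median of -0.76 below all 10000 random lists.

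Fold changes followed transcript length across genes in both comparisons that contain WT DP1. Spearman's rho between log2 change and the length of the longest transcript was 0.51 in Hdac3KO against WT DP1 and 0.41 from DP1 to DP2 in WT. The comparisons without WT DP1 gave 0.02 in DP2 and -0.15 in Hdac3KO. Fold changes also followed GC content, with rho of -0.26 in DP1 and 0.32 in DP2 between genotypes, -0.43 from DP1 to DP2 in WT and 0.22 in Hdac3KO. Ribosomal protein genes, which are short, had medians of -0.80 and -1.20 in the comparisons with WT DP1 and of 0.25 and -0.06 in the others.

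**Figure D5:**
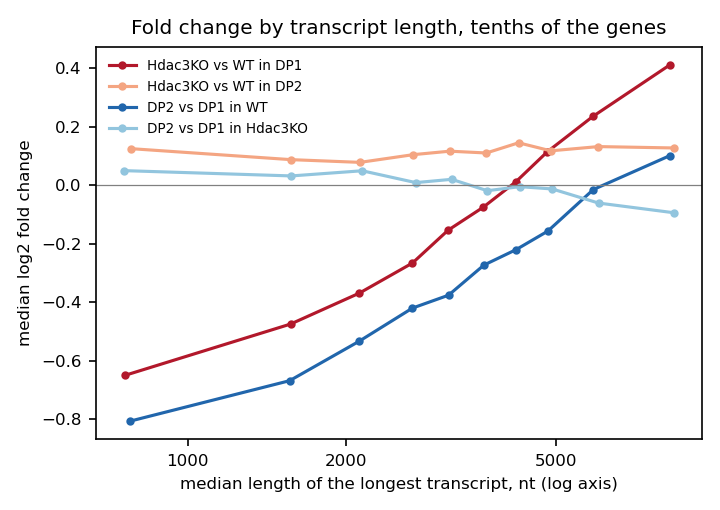
Lines give the median log2 fold change in 10 equal groups of the genes ordered by the length of the longest transcript (nucleotides, log axis) in the 4 comparisons. The medians run from -0.65 in the group of the shortest to 0.41 in that of the longest transcripts in Hdac3KO against WT DP1 and from -0.81 to 0.10 from DP1 to DP2 in WT, against 0.12 to 0.13 and 0.05 to -0.09 in the comparisons without WT DP1.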

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

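The tests of the length trend against growth genes and against GC content were written before their results were seen, and all other tests of explanations here were chosen after the patterns had been seen. The results below stand out because the effect of Hdac3 loss differed between DP1 and DP2, by the test of the difference itself. The genotype tables gave 91 genes with a higher and 120 with a lower effect in DP2, and the stage tables, which rest on the same libraries, gave 206 and 106. Relative to the median genes these splits were 34 and 333, and 24 and 347, with the GC trend removed 13 and 71, and 11 and 57, and with the SE multiplied by 1.5 the normal test gave 0 calls by either route (413 and 473 at an unadjusted p of 0.05), so these counts depended on the settings. With the length trend removed 8 and 98 were called by the genotype tables, 4 and 68 of them called before, and 11 and 122 by the stage tables, 9 and 71 of them called before.

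The named genes below had lower effects in DP2 than in DP1 by the genotype tables. Of all 120 such calls 68 were also made with the length trend removed. The differences on the log2 scale were -3.90 for Cd302, -3.69 for Cd53, -2.06 for Cd209c, -2.05 for Cd226 and -1.35 for Ccr4. Those of the survival factor Bcl2, the phosphatase gene Inpp4b and the transcription factor genes Tox2 and Lef1 were -2.60, -2.33, -2.29 and -1.20. Genes of mitosis were at -1.89 (Cenpe), -1.89 (Kif20b), -1.63 (Cenpf) and -1.60 (Mki67). Only Kif20b among them was also called by the stage route, and Cenpe and Cenpf have long transcripts (7910 and 11130 nt). The remaining lower ones were Spata1 (-2.98), Zfp930 (-2.12), Zfp182 (-2.06), Ppp2r3a (-1.97) and St3gal2 (-1.71).

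Of the genes named here with a higher effect in DP2 by the genotype tables, only Bmf and Shfm1 were also called with the length trend removed. These higher effects included members of the BCL2 family, Bad at 2.02, Bmf at 1.58 and Bcl2l1 at 1.23. Surface molecules were Cldn4 at 2.71, Epcam at 2.39 and the coreceptor gene Cd8b1 at 1.28. Metabolic and repair genes were Agxt at 2.65, Ung at 2.09, Galk1 at 1.89 and Pmm1 at 1.86. The others were Ift27 (2.32), Timm13 (2.15), Shfm1 (1.90), Rpl37 (1.86), Rplp0 (1.25), Hist1h4d (1.23) and Endou (1.14).

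By the stage tables the difference is that of the DP1 to DP2 change, Hdac3KO minus WT. Lower values were found for Cd302 (-3.79), Lipi (-3.54), Spata1 (-2.93), Bcl2 (-2.49), Inpp4b (-2.27), Zfp930 (-2.09), Zfp182 (-2.02), Cd209c (-1.99), Ppp2r3a (-1.91) and Kif20b (-1.84). Of the higher values named here only those of Bmf and Cldn4 were also called with the length trend removed. Higher values were found for Cldn4 (2.83), Agxt (2.76), Epcam (2.53), Ift27 (2.44), Timm13 (2.27), Bst2 (2.18), Bad (2.15), C85492 (2.13), Mvk (2.07), Zfp771 (2.05), Galk1 (2.01), Shfm1 (2.004), Pmm1 (1.97) and Rpl37 (1.95). Genes of immune function and survival with smaller differences were Bmf (1.70), Selplg (1.65), Cd8b1 (1.38), Bcl2l1 (1.37), Ltb (1.23) and Irf1 (1.21), beside Rplp0 (1.36).

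Fold changes followed transcript length in both tables that contain WT DP1, with Spearman rho of at least 0.406 across genes, and by no more than 0.15 in size in the tables without it. Ribosomal, histone, cell cycle, housekeeping, glycolysis and mitochondrial ribosome genes and those called in the Hdac3KO stage comparison were left out as genes of growth and division. These genes did not carry the trend, which stayed at a rho of at least 0.404 without them. Most NADH dehydrogenase genes (medians -0.81 in the DP1 genotype and -1.05 in the WT stage comparison) stayed in, so growth genes as a whole were not tested. GC content did not carry all of the length trend, since the partial rho on length given GC was at least 0.324. Fold changes nevertheless also followed GC in each comparison (rho -0.258, 0.325, -0.428 and 0.216), those without WT DP1 included. It may be that the WT DP1 libraries hold fewer reads from long transcripts than the others, but the only test of this, the rho of 0.406, restates the pattern and cannot tell. That WT DP1 cells themselves hold more short transcripts stays open too, as the median of -1.20 for the short ribosomal protein genes from DP1 to DP2 in WT restates the trend, and there are no values per library.

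Xist and the Y-linked genes parted the genotypes in both populations. Genes on X and Y were 3.47% of the DP1 genotype calls and 3.14% of those in DP2, against 3.07% and 3.09% of the tested genes. They were too few to make up most calls whatever the result (at the highest 13.03% and 28.7%), so this share by itself decides nothing. Whether the sex of the animals changed autosomal genes cannot be told apart from the genotype, because both group values of a genotype carry the same pattern, and 2392 autosomal genes were called in DP1. A part of these calls may therefore follow sex, which remains untested.

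Part of the Hdac3 signal was left in Hdac3KO cells. If undeleted cells with WT levels carried all of it, no other transcript could lie below the Hdac3 ratio. In DP2, 54 autosomal genes fell below that ratio by more than the 95% interval of the difference, which argues against undeleted cells as the whole cause there. In DP1, 0 genes fell below the Hdac3 ratio by more than that interval, although 59 of 1186 lower autosomal genes had a smaller ratio. Undeleted cells could contribute there, and the tables do not decide.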

How the results depend on the processing

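Removal of the length trend, removal of the GC trend and omission of genes on X and Y were chosen after the data had been seen, and the other alternatives before. Among the main values of the comparisons, 59 stayed within the bounds set for them under an alternative (counts within 1.5 times of the main count) and 33 moved, and for those that moved the cause was not tested, except where a stricter or looser threshold by itself makes fewer or more calls. At a q of 0.01 the counts were 1300 (DP1 genotype), 618 (DP2 genotype), 1221 (WT stage) and 434 (Hdac3KO stage), and with a log2 change of at least 1 they were 1212, 706, 1602 and 431. The normal p of the deposited statistic gave 1544 genes in DP1 and 1386 in the WT stage comparison, and removal of the length trend 1530 and 1424. Removal of the GC trend gave 1398 in the WT stage comparison, and within the bounds 2146 in DP1, 978 in DP2 and 620 in the Hdac3KO stage comparison, of which 1779, 788 and 576 were main calls, and in DP2 the majority turned to 393 higher and 585 lower. The DP2 genotype and Hdac3KO stage counts stayed within 1.5 times of the main count with the length trend removed (1077 and 643) and with the normal p (829 and 616). Size alone hid changes here, since the normal p gave 246 higher and 583 lower genes in DP2, against 687 and 461, and 459 of its 829 calls were main calls, as were 405 of the 616. With the length trend removed 925 of the 1077 and 606 of the 643 were main calls, and the DP2 split was 465 and 612. Centring gave 2378, 1076, 1882 and 656 calls, a q of 0.10 gave 3281, 1603, 3246 and 842, joint adjustment over the 4 tables gave 2185, 1272, 2135 and 819, and omission of X and Y gave 2388 in DP1 and 1112 in DP2, all within 1.5 times of the main count. The majority direction nevertheless turned after centring in DP1 (1120 higher and 1358 lower to 1431 and 947), in DP2 (687 and 461 to 463 and 613) and in the WT stage comparison (603 and 1818 to 1177 and 705), because the median gene was not at 0.

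The interaction counts depended most on the settings. The genotype route gave 18 genes at an adjusted p of 0.01, 581 at 0.10, 367 after centring, 533 with SE from the deposited statistic, 106 with the length trend removed and 84 with the GC trend removed, 46 of them main calls. The stage route gave 8 at 0.01, 771 at 0.10, 133 with the length trend removed and 68 with the GC trend removed, 47 of them main calls. With the SE multiplied by 1.5 the normal test of the difference gave 0 genes by either route, with 413 of 10144 and 473 of 9969 at an unadjusted p of 0.05. The Spearman rho of the genotype effects was 0.58 over genes called in either table, 0.44 with the length trend removed and 0.505 with the GC trend removed, and that of the stage changes was 0.53, 0.32 and 0.37, and 0.24 at a minimum of 5 FPKM. Cell type marker calls numbered 24 at a q of 0.01 instead of 38. The purinergic list in Hdac3KO DP2 reversed, from a median of -0.56 before centring to 0.00227 at a minimum of 5 FPKM. Of the list medians 88 of the 95 with a value at that minimum kept their side of the limits of random lists, as did 97 of 104 with the length trend removed and 100 with a pseudocount of 1, and 3 of the 95, 10 of 104 and 0 of 104 medians changed sign. Centring shifts a list and its random lists alike, so it cannot test those limits, and 7 of 104 medians changed sign under it. Lists that went inside the limits at 5 FPKM included TCR-induced genes (percentile 5.2) and NF-kB targets (88.4) in DP1. With the GC trend removed 93 of 104 medians kept their side of the limits and 12 changed sign, and those that went inside included NF-kB targets (96.3) and purinergic genes (10.4) in DP2. Of the 84 named genes 83 kept their side after centring, 80 with the length trend removed, 83 with the GC trend removed (all but Il7r in WT) and 84 with group values from the other tables, while a pseudocount of 1 moved the fold change of 28.

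No paired analysis was possible because the deposited tables hold one value per group, and the labels state no pairing. For the same reason the planned omission of each replicate, the replicate block and the models on values per library were not run. Depth per library is unknown, so what it limits could not be computed.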
